A study of Homo sapiens with 8 samples.

How the data were processed

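Chromatin from MIA PaCa-2 cells, an established line of pancreatic cancer cells, was immunoprecipitated with antibodies against H3K9ac and H3K27ac, acetylated forms of histone H3 found at active promoters and enhancers, and sequenced. Cells were grown as spheroids in a hyaluronan hydrogel under 2 conditions. Astromal gels held no collagen-derived component and were fed plain low-serum medium. Stromal gels held the collagen-derived component and were fed medium conditioned by myofibroblasts from human pancreatic tumours. There was 1 library per mark and condition. The 4 ChIP libraries each had a peak list, and the 4 input libraries are not analysed here on their own.

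Reads were handled with CASAVA 1.8.2, Bowtie and HOMER on build hg19, per the submitters' processing notes. Each list came from 1 library and not from pooled libraries, per the file headers and the labels. For H3K27ac, HOMER called peaks of 1 fixed width against the input at an FDR of 0.001, per the file headers. Those headers ask for at least 4-fold over input and at least 4-fold over the surrounding 10 kb, each with a Poisson p-value of at most 1.00e-04. The filter against the surrounding 10 kb took out 11543 of 27707 putative astromal peaks and 12583 of 30936 stromal ones, and the filter against input took out 1674 and 3259, per the file headers. The H3K9ac lists were annotated with HOMER against hg19, per the file headers, and their calling thresholds are not given in the sources used here. Fold over input is given for H3K27ac only.

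The main signal was the deposited tag count per peak, which the authors had normalised to 10000000 tags. In the H3K27ac lists this signal stood beside raw tag counts or counts scaled to the control library, and the deposited header gave each library's total. In the H3K9ac lists the deposited signal rose in even steps, each the worth of 1 tag. All values lay within 0.1 tag of a whole number of tags, so the step gave tag counts per peak and an estimated depth. Fold over input, fold over the local region and their p-values were used as the authors deposited them, to describe and filter H3K27ac peaks within a list. The deposited fraction of tags in focus and the findPeaks score are also the authors' own values. The score served only to rank peaks within a list and as an alternative level, and its correlation with the tag count was 0.986 in both H3K27ac lists.

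Depth was 3923202 tags for astromal and 7569791 for stromal H3K9ac, both estimated, and 13453902 and 17190695 for H3K27ac. The median peak held 9, 20, 18 and 20 tags in that order, so a peak of the astromal H3K9ac list rested on few tags. Intervals of shares and of tag ratios are exact Clopper-Pearson intervals at 95%, and those of observed over expected counts are exact Poisson intervals. Both kinds cover counting error only. Intervals of medians and frequency ratios come from bootstrap draws of peaks or promoters. They cover the spread across peaks or promoters taken as independent, although some genes share a promoter. No interval covers variation between cultures or libraries. With 1 library per group no difference between conditions was given a p-value.

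Positions of transcription start sites (TSSs) were rebuilt in hg19 from the H3K9ac lists, which name a transcript and its distance for each peak. Of 14953 transcripts, 7889 were solved from peaks on their own, 1367 from other transcripts of the gene, and 4832 kept both positions, since the strand was unknown. A further 861, of unknown strand and with no peak within 1 kb, were left out, and 4 gave conflicting positions. This placed 10229 protein-coding genes, 10222 of which matched a RefSeq gene table that was used for names and gene types only. A gene entered only if an H3K9ac peak of either list lay nearest to it. The placed genes are therefore those with H3K9ac somewhere near, mostly from the longer stromal list, and nothing is said of genes that were not placed. H3K27ac peaks were assigned to the same TSSs.

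Peaks were shared when they overlapped by at least 1 bp, checked with bedtools 2.31.1. Chance overlap came from 100 circular shifts of peak positions along each chromosome. A promoter peak had its centre within 1 kb of a TSS. Levels at shared promoters were log2 ratios, stromal over astromal, of the normalised tags summed over promoter peaks, centred on the median of all shared promoters. A gene was called higher or lower when the centred ratio was at least 2-fold and its interval left out 0. On simulated counts, 100% of 4-fold rises were called in either mark, 80% (H3K9ac) and 90% (H3K27ac) of 4-fold falls, and 48% (H3K9ac) and 50% (H3K27ac) of 2-fold rises. For 2-fold falls the shares were 38% and 48%, and among unchanged genes 2.84% and 1.49% were called. The simulation redrew the summed tags and held the peaks of each promoter fixed. A peak that passes the caller in only 1 library by chance is not covered, so false calls can be more frequent than these shares.

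The 22 gene lists, the promoter and overlap settings, the rule for naming genes and the main alternatives were fixed before the data were examined. For each list, the shares of stromal-only and astromal-only promoters and the median centred ratio were set among 10000 random lists of the same size, drawn from genes in the same of 5 classes of tag count. A list stood apart when a percentile lay in either 2.5% tail. This gave 114 percentiles, of which 5.7 would lie in the tails by chance if each could reach both tails. Shares of few genes often cannot, so 5.7 can overstate the number expected. Genes were named as follows: the 8 promoters of each list without a partner in the other list that had most tags; the 6 highest and 6 lowest ratios among shared promoters with at least 20 tags in each library; up to 4 members per gene list; and up to 8 genes found in the same condition alone by both marks. Genes with provisional symbols, readthrough genes and chromosome Y were excluded from naming, and results for some genes are not reported here. Distal H3K27ac peaks, more than 2.5 kb from any placed TSS, were joined within 12 kb and ranked within each list. Alternatives covered the overlap rule, the promoter window, stricter peak thresholds, centring, the highest peak in place of the sum, and unmatched random lists. Thinning of the deeper library, gene lists by highest peak, the location of stronger peaks and the expectation within tag classes were added after seeing the data. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.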

Results

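H3K9ac and H3K27ac were profiled in MIA PaCa-2 spheroids grown in a hyaluronan gel, either without stromal cues (astromal) or with a collagen-derived gel component and medium conditioned by tumour myofibroblasts (stromal). The design asks how the stromal setting changes histone acetylation in the cancer cells. Each of the 4 combinations of mark and condition was 1 library, so there was no replicate check of any difference. The H3K9ac lists held 7141 astromal and 20326 stromal peaks, covering 1.44 and 4.29 Mb, and the H3K27ac lists 14489 and 15093 peaks, covering 2.85 and 2.64 Mb. Depth, estimated from the values, was 3923202 tags for astromal and 7569791 for stromal H3K9ac. For H3K27ac it was 13453902 and 17190695 tags. Levels are the authors' tags per peak, normalised to 10000000 tags of the library. Intervals in brackets are 95% intervals that cover counting error or, for medians and frequency ratios, the spread across peaks or promoters. None covers variation between libraries.

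The stromal H3K9ac peak list covered far more of the genome than the astromal one. Most sites of the astromal list were found again, 5411 of 7141 peaks (75.8%, 74.8 to 76.8), whereas they made up 26.6% (26.0 to 27.2) of the stromal list. The 14915 stromal-only peaks lay mainly at promoters, with 72.4% (71.7 to 73.1) within 1 kb of a TSS, 11.3% in gene bodies and 16.3% outside genes. Peaks shared by both lists were at promoters more often, at 87.7%, and the 1730 astromal-only peaks at 80.9%. Stromal-only peaks with at least 29 tags, the median of shared ones, were at promoters in 87.4%, so the contrast went with peak strength. Shifted positions gave 25.8 shared peaks on average and at most 40. Stromal-only peaks were weaker than shared ones, with a median of 22.5 against 38.3 normalised tags (17 against 29 tags). The 5th percentile of peaks was 17.8 normalised tags in the astromal list and 13.2 in the stromal one. Weak sites could thus go uncalled in the astromal library, and absence from its list is not a measured absence of H3K9ac. At shared sites the stromal level was higher in 90.5% of peaks, by a median of 0.64 on the log2 scale (1.55-fold, interquartile range 0.34 to 0.93). The stromal library had 1.93 times the depth and 3.30 times the share of tags in peaks (5.81% against 1.76%). Thinned to the astromal depth, it still had 2.67, 2.29 and 1.81 times as many peaks with at least 5, 7 and 9 tags as the whole astromal list. Thinning kept the peaks called at full depth and did not call them again, which can favour the stromal list.

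At protein-coding promoters this gave 4588 genes with H3K9ac in the stromal list only and 35 in the astromal list only, beside 5240 in both and 366 in neither. The strongest stromal-only promoter was that of PLEKHG5, with 130.7 normalised tags (99 tags) in 4 peaks, the highest in an intron of chromosome 1 from 6550243 to 6550453 (hg19). The transcription factor gene NFIC and the pair MAF1 and SHARPIN, which share a promoter, each reached 128.1 (97 tags). MAF1 represses RNA polymerase III and SHARPIN belongs to the linear ubiquitin ligase complex. LRRC41 had 117.6, and the LIM-domain cofactor gene LDB1 and the neighbours DDIAS and PRCP 113.6 each. In the astromal list alone stood DHRS3, a retinal reductase, with 48.4 normalised tags (19 tags), its stronger peak on chromosome 1 from 12677819 to 12678019. CDKN1B, which encodes a cyclin-dependent kinase inhibitor, followed with 45.9 (18 tags) in a 5′ UTR peak on chromosome 12 from 12870538 to 12870738. HEXIM1, an inhibitor of transcription elongation, and the histone gene HIST1H3D had 35.7 each. IGF2BP3 and TMSB4X had 33.1 each, and IRS1, the insulin receptor substrate, and the nuclear receptor gene NR2F1 30.6 each. With a window of 200 bp the 2 numbers became 2344 and 597. Of astromal-only genes there were 19 with a window of 2.5 kb, and 13 when no stromal peak lay within 5 kb. Most of the 35 thus had a stromal H3K9ac peak nearby. Placed genes came from the H3K9ac lists, which keeps the number with no peak low.

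**Figure D1:**
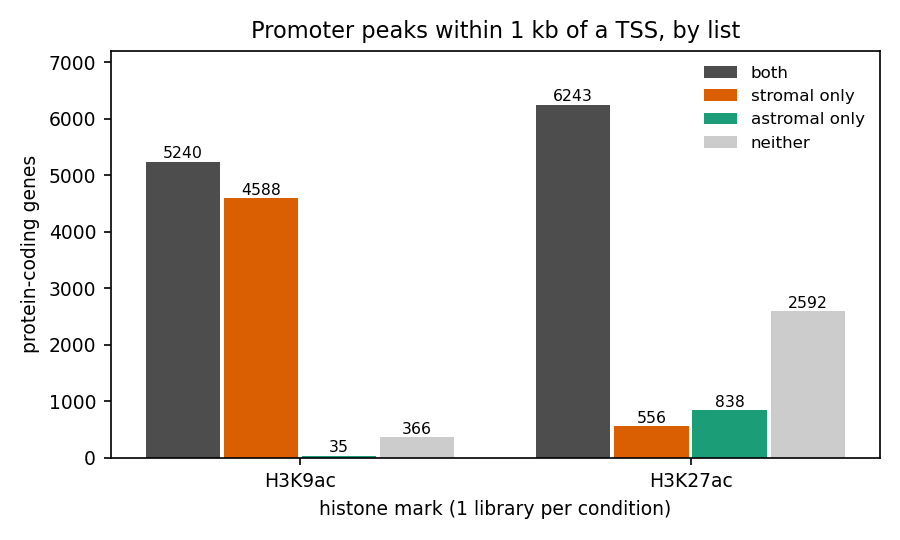
Number of protein-coding genes (vertical axis) with a promoter peak in both lists, in the stromal list only, in the astromal list only or in neither, for each mark with 1 library per condition. H3K9ac shows 4588 stromal-only against 35 astromal-only genes, and H3K27ac 556 against 838.

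Where both libraries had promoter H3K9ac, the stromal level was higher by a median of 1.03 on the log2 scale when peaks were summed, and by 0.69 at the highest peak. Against that median, 188 genes were higher and 220 lower, and 4832 were not called. On simulated counts with the peaks held fixed, 2.84% of unchanged genes were called. Without centring the split was 2455 higher and 6 lower. Those 6, a group chosen after their values were seen, were TGIF1, TM4SF18, TUBGCP2, DNAH7, AKIRIN2 and PNN. TGIF1, a corepressor of TGF-beta signalling, had 86.7 astromal and 15.9 stromal normalised tags (34 and 12 tags), which put it at −3.48 after centring (−4.57 to −2.50) and −2.22 at the highest peak. TM4SF18, a tetraspanin-like membrane protein, had 79.0 and 33.0 and fell by 2.29 after centring (−3.11 to −1.48). Among promoters with at least 20 tags in each library, the next lowest ratios were those of AKIRIN2 (−2.04), the splicing-associated gene PNN (−2.04), the histone gene H2AFJ (−1.94), the transporter gene SLC22A4 (−1.93) and MSL2 (−1.89), all called lower. Of these, AKIRIN2 was also called at its highest peak (−1.12), and TM4SF18 (−0.58), PNN (−0.51), H2AFJ (−0.09), SLC22A4 (−0.74) and MSL2 (−0.64) were not. The highest ratios among promoters with at least 20 tags in each library were those of PCBD2 (0.51), RSBN1L (0.48) and PPIL3 (0.48). The interferon receptor gene IFNAR1 (0.47), BANP (0.46) and NBPF1 (0.41) followed, and none of these was called. Only 629 of the 5240 shared H3K9ac promoters had at least 20 tags in each library. The median astromal H3K9ac peak held 9 tags, so this rule favours promoters that are high in the astromal library. It can thus lower the ratios listed, and large falls beside small rises there do not show that losses outweighed gains. All 188 higher calls were at genes with more stromal than astromal peaks, and 146 of the 220 lower calls at genes with fewer. By the highest peak alone, 10 genes were higher and 35 lower.

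**Figure D2:**
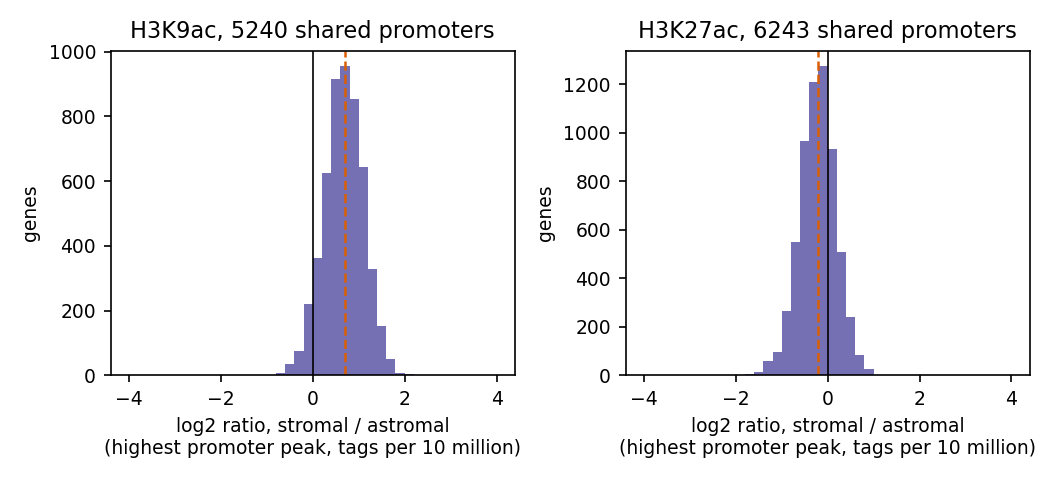
Log2 ratio, stromal over astromal, of the highest promoter peak in normalised tags (horizontal axis) against the number of genes (vertical axis), for the 5240 H3K9ac and 6243 H3K27ac promoters found in both lists. The dashed line is the median, 0.69 for H3K9ac and −0.21 for H3K27ac.

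H3K27ac was much closer between the conditions. The lists shared 8813 astromal peaks (60.8%, 60 to 61.6) with 8814 stromal peaks (58.4%, 57.6 to 59.2), where shifted positions gave 35.9 on average and at most 50. At shared peaks the stromal level was lower, by a median log2 ratio of −0.18 (interquartile range −0.45 to 0.08), and higher in 31.4% of them. Stromal peaks were 175 bp wide and astromal ones 197 bp, a log2 ratio of −0.17, so the shift is about that of the width of the counted window. The 5676 astromal-only and 6279 stromal-only peaks were weaker than shared ones (15 against 20 tags and 17 against 22 tags). They lay at promoters in 61.8% and 54.8% of cases, against 74.3% of shared peaks. The stromal library had 1.28 times the depth and 0.909 times the share of tags in peaks.

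Promoter H3K27ac was found in both lists at 6243 genes, in the stromal list only at 556, in the astromal list only at 838 and in neither at 2592. The strongest stromal-only promoter was that of ECT2, which is needed for cytokinesis, with 53.6 normalised tags (92 tags), its higher peak on chromosome 3 from 172468007 to 172468181. SETD5 (47.7), TM4SF18 (43) and the histone genes HIST1H2AH and HIST1H2BK, which share a promoter (41.9), came next. The CBP/p300-binding coactivator gene CITED2 had 38.4, and HMMR, the hyaluronan-mediated motility receptor, shared 36.0 with NUDCD2. In the astromal list alone stood SMG9, of nonsense-mediated decay, with 58.7 (79 tags). The glycolytic gene GAPDH had 53.5 (72 tags), its higher peak on chromosome 12 from 6642779 to 6642975. DDIT4, an inhibitor of mTOR signalling, and the Polycomb gene PCGF1 had 49.8 each, GPBP1 and TSC22D2 48.3 each, and the pair AIMP2 and PMS2 43.1. All of these except CITED2 had H3K9ac in both lists. Among promoters of 1 list with at least the median tags of shared ones, 98 astromal and 66 stromal, 31.6% and 36.4% had a fold over the surrounding 10 kb below 5, close to the required 4, against 2.08% and 2.71% expected from shared promoters. Absence from a list is thus not a measured absence of tags.

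At shared H3K27ac promoters the median log2 ratio was −0.18, near the −0.17 of the peak widths, and against it 321 genes were higher and 383 lower. On simulated counts with the peaks held fixed, 1.49% of unchanged genes were called. Without centring, and so with the difference in width, the split was 169 and 577. Among promoters with at least 20 tags in each library, the ubiquitin ligase gene RFFL was highest at 2.08 (1.51 to 2.68), followed by the angiogenic factor gene VEGFA at 1.84 (1.19 to 2.55), the quinone reductase gene NQO1 at 1.72, DCTN6 at 1.67, PRTFDC1 at 1.61 and the purine synthesis gene PFAS, which shares its promoter with CTC1, at 1.61. Each had 1 astromal and 3 or 4 stromal peaks, and at the highest peak they ranged from 0.22 to 0.43. The adaptor gene NCK1 was lowest of these promoters at −1.66, followed by SLC25A13, the mitochondrial aspartate and glutamate carrier, at −1.63 (−2.37 to −0.94). GPN3 (−1.56), the homeobox gene PKNOX1 (−1.56), the deubiquitinase gene USP34 (−1.54) and the lipid transfer gene STARD7 (−1.47) were also called lower. Of these 6, SLC25A13 (−1.37) and PKNOX1 were called at the highest peak as well. By that measure 30 genes were higher and 54 lower, and 15 and 32 were called the same way by both. Among these, chosen after their values were seen and with fewer than 20 stromal tags, were the DNA exonuclease gene EXO1, which fell by 1.85 (35.7 against 8.73 normalised tags), the kinase gene JAK2, which fell by 2.07 (30.43 against 6.4), and SDHA of succinate dehydrogenase, which fell by 1.47. Of the 321 higher calls 311 were at genes with more stromal peaks, and of the 383 lower calls 354 at genes with fewer.

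Genes of central metabolism had condition-only promoter peaks of either mark. In glycolysis, 12 of 20 placed genes had promoter H3K9ac in both lists and 6 in the stromal list only, among them ENO2 (66.1 normalised tags), HK1 (48.9), the glucose transporter gene SLC2A1 (42.3) and PFKFB4 (34.3). LDHA, lactate dehydrogenase A, was the 1 member called, at −1.54 (35.7 astromal and 25.1 stromal normalised tags) and −1.20 at its highest peak. For H3K27ac, GAPDH, TPI1, ENO2 and SLC16A3 were in the astromal list only and SLC2A1, GPI and PFKFB3 in the stromal list only. In pentose phosphate and nucleotide synthesis, 14 of 26 genes had H3K9ac in both lists and 12 in the stromal list only, led by PGD (80.6) and the pair PAICS and PPAT (66.1). PGD and IMPDH2 were among those with H3K27ac in the astromal list only, TALDO1 had it in the stromal list only, and PFAS was called higher and GMPS lower. Of 26 genes of the TCA cycle and glutamine use, 8 had stromal-only H3K9ac, including IDH1 (80.6), DLST (54.2) and PDHA1 (39.7). PC and ME2 had astromal-only and PDHA1 and SUCLA2 stromal-only H3K27ac. In H3K27ac SDHA and DLST were called lower and GOT2 higher. None of these lists stood apart from random lists of the same tag levels in either mark.

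Genes of acetyl-CoA and fatty acid metabolism, the supply of acetyl groups for histones, had stromal-only H3K9ac at 10 of 18 promoters, among them ELOVL5 (67.4), FASN (55.5), CPT2 (52.8) and the citrate carrier gene SLC25A1 (51.6). The desaturase gene SCD was in the astromal list only. HADHA (40.2), ACSS2 (8.92) and SLC25A1 (8.18) had astromal-only H3K27ac, and SREBF1 (29.1) and ACSL3 stromal-only H3K27ac. ACADM was called lower in H3K9ac, and ACLY, which makes acetyl-CoA from citrate, in H3K27ac. Cholesterol synthesis had 11 of 21 stromal-only H3K9ac promoters, led by LSS (68.7), IDI1 (56.8) and SREBF2 (55.6), and 16 of 21 with H3K27ac in both lists, with MVK and MSMO1 astromal only and HSD17B7 stromal only. CYP51A1 was called lower in H3K9ac. In the serine, one-carbon and amino acid response list, 7 of 21 promoters were stromal only for H3K9ac, led by MTHFD1L (87.2), and SHMT1 was the 1 astromal-only promoter for H3K27ac. DDIT3, the stress transcription factor CHOP, was at −1.35 and PYCR1 at −1.32 in H3K27ac, both called lower, though not at their highest peaks (−0.11 and −0.34). In H3K9ac DDIT3 was called lower and SESN2 higher. Of the autophagy and lysosome genes, 7 of 25 had stromal-only H3K9ac, among them CTSD and LAMP1. MAP1LC3B and ATG7 had stromal-only and GAA astromal-only H3K27ac, and LAMP2 was called lower. SQSTM1 was called higher in H3K9ac. None of these 4 lists stood apart by the summed tags within 1 kb. By the highest peak the cholesterol median and the stromal-only share of autophagy genes (percentile 1.83) lay in the lower tail for H3K9ac, and with a window of 2.5 kb the astromal-only share of acetyl-CoA genes lay in the upper one.

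Cell cycle genes had stromal-only H3K9ac at 19 of 27 promoters, including MCM7 (71.3), MCM2 (58.1), CDC20 (54.1) and CCNB1 (48.9), at percentile 96.7 of random lists, short of the upper tail. Against random lists not matched on tags the share was at 99.2. Their H3K27ac was in both lists at 16 of 27, with TOP2A, MCM6 and PLK1 astromal only, MKI67 stromal only and MCM2 called lower. Immediate early and growth factor response genes had 9 of 23 stromal-only H3K9ac promoters, led by IER3 (81.9), FOSB (42.2) and ETV4 (40.9). SPRY2, PHLDA1 and KLF6, the first of them an inhibitor of growth factor signalling, were astromal only, a share of 13.6% at percentile 100 of random lists, and JUN was called lower. For H3K27ac the list had 8 promoters in both lists and SPRED1 astromal only, and DUSP1 fell by 1.12, though not at its highest peak (−0.15). In the TGF-beta and YAP target list, 9 of 21 genes had stromal-only H3K9ac, led by ID1 (75.3) and SMAD6 (38.3). TGIF1 (33.4) and TEAD1 (9.66) had astromal-only H3K27ac.

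Epithelial and mesenchymal genes showed condition-only peaks in both directions. Of 8 placed epithelial and ductal genes, KRT8 (26.4), KRT19 and FOXA1 (19.8) had stromal-only H3K9ac, and the splicing regulator gene ESRP2 (20.4) and the tight junction gene CLDN4 (17.8) astromal-only H3K9ac. The stromal-only share, 37.5% against a random median of 75%, lay at percentile 0.435 and the astromal-only share at 99.9. With a window of 2.5 kb neither share was in a tail (2.87 and 48.4), and without matching the stromal-only share was at 31.8 and the astromal-only share at 100. The median ratio of its 3 shared promoters, at percentile 2.71 here, lay in the lower tail without matching (1.03) and at 2.5 kb (1.56). By the highest peak it was in the tail only with random lists matched on that peak (2.3), and at 4.57 with the matching of the main settings. SOX9 had astromal-only H3K27ac (14.1) and MUC1 fell by 1.06, though not at its highest peak (−0.03). Of 6 placed mesenchymal genes, VIM (92.5), SNAI1 (47.6), S100A4 (21.1) and LOXL2 (19.8) had stromal-only H3K9ac. VIM, the intermediate filament vimentin, also had stromal-only H3K27ac (20.4), whereas S100A4 (38.7) and LOXL2 (20.1) had it in the astromal list only. That share of 2 of 5 genes was at percentile 98.7, and at 94.8 without matching. Matrix, integrin and adhesion genes had 12 of 20 stromal-only H3K9ac promoters, among them TIMP1 (63.4), TIMP2 (55.5) and ITGAV (52.8). ITGB4 (25.0) and DDR1 had stromal-only and the hyaluronan receptor gene CD44 (18.6) and PXN astromal-only H3K27ac, and TIMP2 was called lower. The ESRP2 and CLDN4 peaks held 8 and 7 tags, and 12 genes each of the epithelial and mesenchymal lists were not placed.

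Inflammatory genes had stromal-only H3K9ac at 9 of 16 promoters, among them SOCS3 (46.3) and the chemokine genes CXCL2 (41.0), CXCL3 (38.3) and CXCL1 (34.3). CXCL1, CXCL5 and NFKB2 had stromal-only and CXCL3, RELB and SOCS3 astromal-only H3K27ac, and STAT3 was called lower. Interferon response genes had 13 of 18 stromal-only H3K9ac promoters, including STAT2 and IRF1 (44.9 each), HLA-B (43.6) and ISG15 (34.4). Their 5 shared promoters had a median centred H3K9ac ratio of 0.71, percentile 98.9 of random lists, and of 0.36 at the highest peak. The latter was at percentile 94.1 with the matching of the main settings. With random lists matched on the highest peak it was at 97.485, just short of the tail. In H3K27ac the median was within the random range by summed tags (percentile 81.8) and at 0.52 by the highest peak, percentile 100. No interferon gene was called. ISG15 and DDX58 had stromal-only and IRF1 astromal-only H3K27ac. In the hypoxia list 10 of 15 genes had stromal-only H3K9ac, led by MXI1 (62.1), INSIG2 (48.8), ERO1L (46.2) and ANKRD37 (42.3). BHLHE40 (12.8), ERO1L (7.56), NDRG1 and ANKRD37 also had stromal-only H3K27ac, 40% of the members with a peak and percentile 98.3, while DDIT4 and MXI1 were astromal only, VEGFA was called higher and BNIP3L lower. The share was within the random range with a window of 2.5 kb. NRF2 targets had 9 of 20 stromal-only H3K9ac promoters, led by SRXN1 (72.7), with GCLM and HMOX1 stromal only, GSR astromal only and NQO1 called higher for H3K27ac.

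Enzymes and readers of histone acetylation had H3K9ac in both lists at 17 of 26 promoters and in the stromal list only at 9, among them the deacetylase gene HDAC3 (74.0), KAT6B (60.7), BRD3 and KAT8 (48.9 each). The acetyltransferase genes EP300 (20), KAT2A (15.6) and KAT6B (8.92) had astromal-only and HDAC9 (28.5) and KAT8 stromal-only H3K27ac. Housekeeping genes showed the same kinds of difference. Of 22, SNRPD3 (72.6), TFRC (66.0), EMC7 (55.5), HPRT1 (39.6), VCP and CHMP2A had stromal-only H3K9ac. For H3K27ac CHMP2A was stromal only, REEP5 and TBP were astromal only, and PPIA, SDHA and SNRPD3 were called lower, PPIA at −1.70. Among 19 fibroblast markers 5 were placed, and COL1A2 (30.4), ACTA2 (29.0), COL1A1 (17.2) and MMP11 (11.9) had stromal-only H3K9ac. COL1A2 had H3K27ac in both lists and the other 4 placed markers in neither. No immune or endothelial marker was placed, and of the acinar and endocrine markers PAX6 alone, with stromal-only H3K9ac (51.5) and H3K27ac in both lists. Over all lists, 6 of 114 percentiles lay in the tails, where 5.7 would be expected by chance if each could reach both tails. Many could not: the cell cycle list, with 0 astromal-only H3K9ac promoters, lay at percentile 43.6 for that share. The number expected can thus be lower, and 6 against 5.7 does not show that chance accounts for the 6.

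The marks overlapped at many sites, and promoters with stromal-only H3K9ac were more often in 1 H3K27ac list alone, of either condition, than independent lists would give. Of H3K27ac peaks, 29.4% in the astromal and 53.7% in the stromal library overlapped an H3K9ac peak, and of H3K9ac peaks 59.7% and 39.9% overlapped H3K27ac. Among 7624 genes with both marks, 360 were stromal only in both, where independent lists would share 198.0, a ratio of 1.82 (1.64 to 2.02). Weak promoters are missed more often in either mark, and within 5 classes of the H3K27ac tag count 319.2 were expected, a ratio of 1.13 (1.01 to 1.25). The strongest of the 360 genes that were stromal only in both were VIM, with H3K9ac in an intron on chromosome 10 from 17270852 to 17271062 and H3K27ac from 17269874 to 17270048, and GSN, the actin-severing protein gelsolin (84.5 and 16.3 normalised tags). TRMT11 (80.6 and 18.0), HIST4H4 (66.1 and 23.9), PRR12 (72.6 and 15.7), CITED2 (46.2 and 38.4), SERTAD1 (58.1 and 25.6) and the elongation factor gene EEF1A2 (74.0 and 8.14) followed. Astromal only in both were 4 genes, against 1.75 expected. These were DHRS3 (48.4 and 11.9), HOXB2 (22.9 and 27.5), IKZF2 (20.4 and 14.1) and SLCO4A1 (17.8 and 8.92). The opposite class, stromal only in H3K9ac and astromal only in H3K27ac, held 461 genes against 299.0 (1.54, 1.40 to 1.69), or 454.9 within classes of the H3K27ac tag count (1.01, 0.923 to 1.11). Across the 4321 genes with both marks in both lists, Pearson's correlation of the 2 log2 ratios was 0.01 and Spearman's 0.01, and at the highest peak −0.04 and −0.02, across genes, which are not independent replicates. At shared peaks the ratios of either mark spread less than simulated counting error (0.896 and 0.928 times its SD). The simulation kept counts down to the lowest tag number of each list, so it can overstate that error. How much of the spread lies beyond counting error is thus unknown, and correlations near 0 do not show the changes to be unrelated. At the 4588 stromal-only H3K9ac promoters, H3K27ac was present in 51.7% (50.2 to 53.1) in the astromal and 49.5% (48.0 to 50.9) in the stromal list.

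The highest distal H3K27ac domains of each condition mostly had a partner in the other. There were 3669 astromal and 4216 stromal distal peaks, which formed 2626 and 2824 domains. Of the 100 highest of each list 50 overlapped, and 93 astromal and 98 stromal ones overlapped a domain of any rank in the other list. The highest in both lists lay on chromosome 1 near CROCC, from 17215781 to 17241699 in the astromal list with 213.2 normalised tags and from 17215602 to 17231651 in the stromal list with 193.7. A domain near NRROS on chromosome 3 (133.1 and 112.8) was also among the highest of both. Regions without any partner, picked after their values were seen, included a stromal domain on chromosome X from 13415713 to 13447134 (83.8) and an astromal domain on chromosome 21 from 36589555 to 36605797 (66.9), 176.1 kb from the placed TSS of the transcription factor gene RUNX1. A domain can hold the promoter of a gene that was not placed, and the filter against the surrounding 10 kb works against broad domains.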

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

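The tests of the level at shared H3K9ac peaks and of H3K9ac at strong 1-list H3K27ac promoters were chosen after their results were seen.

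The share of tags in peaks was 3.30 times as high in the stromal as in the astromal library for H3K9ac and 0.909 times as high for H3K27ac, a contrast between marks that was not tested for lack of replicates. These are sums over peaks called in each list, 7141 astromal of 201 bp and 20326 stromal of 211 bp for H3K9ac, and 14489 of 197 bp and 15093 of 175 bp for H3K27ac, where the width alone is at a log2 ratio of −0.17. Greater depth alone is argued against, since thinning left at least 1.81 times as many stromal peaks as the astromal list holds, and since the level per 10000000 tags, which depth does not change, had a median log2 ratio of 0.64 at shared peaks. A gain of H3K27ac peaks at stromal-only H3K9ac promoters is argued against, since these peaks were 0.957 times (0.934 to 0.980) as frequent in the stromal list. That is about the 0.961 times at promoters with H3K9ac in both lists. Presence of a peak does not measure level, so a small gain in H3K27ac level is not excluded. Where H3K27ac was in both lists, its median centred log2 ratio at the highest peak was 0.04 at stromal-only and −0.01 at shared H3K9ac promoters. A better yield of the stromal immunoprecipitation, which would raise every peak by 1 factor, and a rise of H3K9ac alone in stromal cultures both stay open and cannot be told apart. The spread of the log2 ratios at shared peaks, 0.896 times that of simulated counting error, does not decide it. Only 1 library per condition was compared with that error, and H3K27ac gave 0.928. A spread below the simulated error also means that the simulation can overstate it.

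H3K27ac promoters with many tags in 1 list and no peak in the other numbered 164, ECT2, SMG9, GAPDH and DDIT4 among them. Removal of the missing peak by the filter against the surrounding 10 kb stays open and is a candidate explanation, because a fold over that region below 5 was 14.4 times (11.3 to 17.7) as frequent as at shared promoters of the same tag number. A peak of the other list just outside the promoter window was within 5 kb at 47.6% of them, too many to exclude and fewer than needed to account for most, so this part cannot be told apart. A change in H3K27ac between the cultures also stays open and cannot be told apart: the median H3K9ac log2 ratio differed between stromal-only and astromal-only promoters by −0.0734 (−0.270 to 0.0843, 109 promoters), but at shared peaks the ratios of either mark spread no more than counting error gives (0.896 and 0.928 times its SD), so H3K9ac was not shown to follow H3K27ac and this difference excludes nothing.

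The classes of the marks also crossed: 461 promoters had H3K9ac in the stromal list only and H3K27ac in the astromal list only, a difference between marks that was not tested, and near the 454.9 expected within classes of H3K27ac tags. Of 34 shared promoters called in both marks, 21 were called in opposite directions and 13 in the same direction, also untested, and by the highest peak 0 genes were called in both marks, in either sense. ANKRA2 and UTP15, both called the same way, share 1 promoter. Examples of opposite calls by summed tags are TFAM, the mitochondrial transcription factor (1.37 in H3K9ac and −1.21 in H3K27ac), STARD7, a lipid transfer protein (1.25 and −1.47), and RINT1 (1.39 and −1.83). DDIT3 was called lower in both (−1.66 and −1.35), and was at −0.46 and −0.11 at its highest peaks. All these directions are relative to the median of shared promoters, 1.03 in H3K9ac and −0.18 in H3K27ac. A promoter called lower in H3K9ac can thus have a stromal level near its astromal one.

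Outside the protein-coding promoters, H3K9ac lay within 1 kb of the TSS of 378 of 540 placed non-coding genes with no placed protein-coding TSS within 5 kb. Protein-coding genes that were not placed, such as ENO1 and CEBPB beside ENO1-AS1 and CEBPB-AS1, can still lie near. Of the 378, 177 had it in both lists, 198 in the stromal list only and 3 in the astromal list only. Genes were placed from the H3K9ac lists, and transcripts of unknown strand only with a peak within 1 kb. The share of 378 in 540 is thus largely set by the placement. Among the strongest were LINC00910, at 170.8 astromal and 289.3 stromal normalised tags, and the small nucleolar RNA host gene SNHG16, at 84.1 and 96.4.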

How the results depend on the processing

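The thinning of the stromal library, the expectation within 5 classes of H3K27ac tags, the gene lists by highest peak and the location of stronger peaks were alternatives chosen after seeing the data. Of 69 values under alternatives, 27 stayed within the spread allowed, 41 moved and 1 reversed. The cause was not tested except where the construction gives it, such as fewer peaks or a wider window. No paired analysis was possible because each group holds 1 library. A fold over input of at least 8 was not run for H3K9ac or for the relation between marks, since the H3K9ac lists carry no such fold, and their score is the tag signal itself.

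The share of astromal H3K9ac peaks found again was 54.7% at 50% reciprocal overlap, 98.3% with gaps up to 1 kb, 74.1% above a common tag floor, 47.3% among equal numbers of top peaks and 73.3% after thinning. The stromal share was 19.2%, 47.1%, 31.7%, 47.3% and 30.5% in that order. For H3K27ac the astromal share was 46.0% at 50% reciprocal overlap, 86.0% with gaps, 57.1% at a fold over input of 8, 57.3% above the floor and 59.3% among top peaks, and the stromal share 44.1%, 86.2%, 53.6%, 61.5% and 59.3%.

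Stromal-only H3K9ac promoters numbered 2344 with a 200 bp window and from 3852 to 4497 under the others. The few astromal-only ones numbered 19 at 2.5 kb, 597 at 200 bp, 76 above the floor, 13 with no stromal peak within 5 kb and 100 after thinning. Stromal-only H3K27ac promoters numbered 851 at 200 bp. Without centring, 2455 H3K9ac promoters were higher and 6 lower, and 169 H3K27ac promoters higher and 577 lower. By the highest peak the counts were 10 and 35, and 30 and 54, with median log2 ratios of 0.69 and −0.21. From scores, which are not scaled to depth, 173 H3K27ac promoters were higher and the median reversed to 0.16. The counting interval was still scaled to depth, which made higher calls harder, so the 173 does not show an effect of the scores alone.

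The ratio of shared stromal-only promoters between marks fell to 1.13 within 5 classes of H3K27ac tags. Promoter location of stromal-only H3K9ac peaks was 77.9% with a 2.5 kb window and 87.4% among peaks with at least 29 tags. Gene list percentiles in the tails, 6 with the settings of the report, numbered 9 without matching, 6 at 2.5 kb and 9 by highest peak, and belonged in part to other lists. Overlapping domains numbered 53 when joined within 4 kb, against 50.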

Other observations

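All gene families here were chosen after the data were seen, and so were their comparisons with random lists, whereas the Spearman test across chromosomes was set before its result was seen.

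Stromal-only H3K9ac was less frequent at promoters of proteasome, mitochondrial ribosomal, respiratory complex III to V and ZNF genes than at other promoters with as many tags. Of 40 placed proteasome subunit genes, 35 had H3K9ac in both lists and 5 in the stromal list only, 12.5% against a median of 37.5% in random lists matched on tags, lower than in all 10000. Mitochondrial ribosomal protein genes had 15 stromal-only promoters of 75 (20% against 38.7%, percentile 0.03) and subunits of respiratory complexes III, IV and V 11 of 43 (25.6% against 41.9%, percentile 0.76). Complex I subunits (11 of 44, percentile 3.42) and cytosolic ribosomal proteins (22 of 75, percentile 7.21) did not stand apart. Zinc finger genes named ZNF had 151 of 373 (40.5% against 47.2%, percentile 0.07). Solute carriers had 97 of 175 (55.4% against 52%, percentile 84.7), and splicing factors 7 of 41 (17.1% against 26.8%, percentile 5.94), with HNRNPUL2 in the astromal list only (percentile 98.2). In H3K27ac the proteasome genes had 1 stromal-only and 3 astromal-only promoters and did not stand apart (percentiles 42.9 and 70.4), whereas ZNF genes had few stromal-only promoters (14 of 318, percentile 1.27) and complex I subunits a median centred log2 ratio of 0.23 (percentile 98.4, and 92.6 at the highest peak).

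Histone genes stood apart in both marks. Of 39 with promoter H3K9ac, 13 were in the stromal list only (33.3%, percentile 2.88, short of the tail). HIST1H1B, with 8 tags, HIST1H3D, with 14, and HIST2H2BE were in the astromal list only (percentile 100 for that share). The 23 in both lists had a median centred log2 ratio of −0.59 (percentile 0.1), though −0.06 at the highest peak (percentile 37.3). The −0.59 is relative to the median of 1.03 over all shared promoters, so it is not a lower stromal level as such. Of 18 with H3K27ac, HIST1H2AH, HIST1H2BK, HIST2H2AA4, HIST2H2BE and HIST4H4 were in the stromal list only, 27.8% at percentile 100 of random lists. HIST2H2BE was thus opposite to its H3K9ac. HIST1H2AH and HIST1H2BK share a promoter, and other pairs of histone genes carry the same values in H3K9ac. Each gene was counted on its own, so the percentiles of both marks treat shared promoters as separate ones. Of 11 placed HOX genes, HOXB2 and HOXA11 had astromal-only H3K9ac (percentile 99.9 for that share) and HOXA13, HOXB6 and HOXC8 stromal-only H3K9ac. HOXB2 and HOXB9 had astromal-only H3K27ac, which did not stand apart (percentile 95.6), and HOXA11 had stromal-only H3K27ac (10.5), opposite to its H3K9ac.

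The share of stromal H3K9ac peaks found again in the astromal list varied by chromosome, from 13.9% on chromosome 4, 14.1% on chromosome 13 and 15.4% on chromosome 15 to 35.6% on chromosome 7. Copy number in the MIA PaCa-2 genome is a candidate explanation, since more copies give more tags and so more peaks past a fixed threshold, and it was tested against the relative input tags at H3K27ac peaks of each chromosome. Across 23 chromosomes Spearman's correlation was 0.637 (two-sided permutation p = 0.00152, 0.00304 after Benjamini-Hochberg adjustment over 4 tests) and 0.53 without chromosomes 15 and 4. Pearson's was 0.852 (permutation p = 2e-05, the smallest 100000 resamples can give, adjusted 8e-05) and 0.77 without them. For H3K27ac, whose lists are deeper, Pearson's correlation was 0.387 (p = 0.0738, adjusted 0.0984) and Spearman's 0.264 (p = 0.223), the difference between marks was not tested, and chromosomes are not independent samples of cells.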
